A study of Mus musculus with 10 samples.

How the data were processed

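RNA was measured by sequencing in 10 libraries of mouse bone marrow hematopoietic stem cells (HSCs), 5 from mice labelled Nup214fl/+ (FL) and 5 from mice labelled Nup214fl/+ with Tie2-Cre (HET). Per the labels' protocols, the cells were sorted as CD48-negative, CD150-positive cells of the LSK gate, which selects lineage-negative marrow cells positive for Sca-1 and Kit. RNA was extracted with a miRNeasy kit, reverse-transcribed and amplified by the Geo-seq method, a protocol for small cell numbers, and made into libraries with a transposase-based kit (TruePrep V2), per the labels' protocols. The labels name no molecular identifiers and no strand marking, so amplification duplicates and antisense transcripts cannot be told from other reads in these values. Whether each library came from a separate mouse is not given in the sources used here, so p-values measure the spread between libraries.

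The deposited values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of each library) per Ensembl gene, as the file's values and column names show, for 52096 genes in all 10 libraries. Per the submitters' processing notes, the genome build was mm10 and the tools included Bowtie 0.12.9, Cufflinks 2.1.1, HTSeq and DESeq2, with no role or order given for each. How reads in shared or overlapping genes were assigned is not given in the sources used here, so values of gene families with near-identical members, such as immunoglobulin segments and histone genes, are uncertain. The authors' p-values and counts were not used here, and the planned description of the authors' own comparison had no values to describe. The planned count model was replaced by the test fixed in advance for FPKM values.

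All 52096 identifiers matched GENCODE M21 (GRCm38, the assembly also called mm10), which supplied symbols, gene types and coordinates. Genes with an FPKM of at least 1 in at least 5 of the 10 libraries were tested, 13041 in all. Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the changes of low genes. HET was compared with FL by limma 3.58.1 in R 4.3.3 with an intensity trend, robust empirical Bayes shrinkage, genotype as the only term and Benjamini-Hochberg adjustment at 0.05. Errors of means are standard deviations over 5 libraries. Nup214 was also compared by an exact two-sided permutation test over the 252 assignments of the 10 libraries.

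Before any value was seen, 41 gene lists, a first set of alternatives and the rule for named genes were fixed. The scalings, protein-coding subset, quality weights, covariates and the fit without both FL 5 and HET 1 were added after the data were seen. The 40 lists with at least 5 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at a correlation estimated per list, and with fry, each adjusted over the lists. The genes named were Nup214, the 6 genes per direction with the smallest p because fewer than 6 genes passed (mean FPKM of at least 1, without predicted Gm genes, Rik clones and pseudogenes), up to 4 members with the smallest p from each list described, fixed genes of ferroptosis and of HSCs, and sex-linked genes. Which lists are described by their members, and whether up to 4 or up to 2 members of each are named, was chosen after the data were seen. Genes named outside this rule are said to be so, and 1 gene that the rule names is not reported here.

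The fit was tested on simulated data made from the means and spreads of the 13041 genes, with 200 genes changed and independent noise. It recovered 71% of the genes changed by 1 on the log2 scale and 95% of those changed by 2, with 9 false calls among 175, and made 0 calls when nothing was changed. Genes of the real libraries vary together, with 42.6% of the variance on 1 principal component. The simulation checks the code of the fit and does not give the recovery or false calls in the real libraries.

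FPKM sums ran from 896054 to 1066190 per library. Read totals were not used here. The smallest non-zero values form steps that give relative depth: for protein-coding genes with 900 to 1200 bases of exon, 1 fragment was worth between 0.045 FPKM per kilobase in FL 4 and HET 4 and 0.11 in HET 3, so HET 3 was the shallowest library by this measure. The steps drifted with gene length, so they were used only to compare libraries, and no intervals for counting error were computed. No 2 libraries were duplicates: at most 0.767% of tested values were identical between any pair.

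Alternatives covered the pseudocount, the filter, shrinkage, scaling of the columns, sample weights, covariates and each library left out. The shrinkage setting does not enter camera, so it repeats the main result of each list in the counts of alternatives below. Annotation tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.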

Results

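Transcript levels were compared between HSCs of mice carrying 1 floxed Nup214 allele without Cre (FL, 5 libraries) and with Tie2-Cre (HET, 5 libraries), where Cre is active in blood and endothelial lineages. Nup214 encodes a nucleoporin of the cytoplasmic face of the nuclear pore. The series title names Nup214 targeting, leukemia stem cells and ferroptosis, the iron-dependent form of cell death driven by lipid peroxidation. The libraries are labelled as HSCs from these mice, and the comparison asks how those with Tie2-Cre and the floxed allele differ from those with the floxed allele alone. No group carries Cre without the floxed allele. Effects of the heterozygous deletion and of Cre itself therefore cannot be told apart.

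Nup214 was lower in HET libraries. The mean of Nup214 was 49.4 ± 13.4 FPKM (SD, n = 5) in FL and 16.8 ± 8.89 FPKM (SD, n = 5) in HET, which is 33.9% of the FL mean. FL libraries 1 to 5 held 65.8, 55.3, 52.2, 43.9 and 30.0 FPKM, and HET libraries 1 to 5 held 31.2, 9.74, 17.4, 16.3 and 9.13 FPKM. All 5 HET libraries lay below the FL median, and FL 5 and HET 1 were the only ones whose order crossed between the groups. The exact two-sided permutation p was 0.0159 for this single gene. In limma across all genes the log2 fold change was -1.59 (SE 0.31), or -1.43 relative to the median of all genes, and the adjusted p of 0.472 did not pass. Without FL 5 its fold change was -1.756 with a limma adjusted p of 0.0183, and over all alternatives the adjusted p ran from 0.000157 to 0.9998. Nup214 (ENSMUSG00000001855) lies on chromosome 2 from 31974436 to 32053975 in GRCm38. The position of the floxed exons is not given in the sources used here, so its value can include reads from outside the deleted part.

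**Figure D1:**
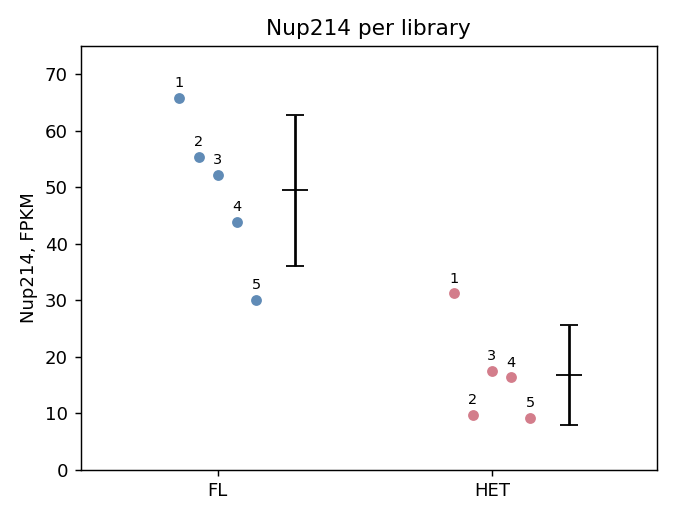
Nup214 in FPKM in each of the 10 libraries, numbered by replicate, with the group mean and SD beside the points. FL values run from 30.0 to 65.8 and HET values from 9.13 to 31.2.

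The nucleoporin list gave no call. Of 30 tested nucleoporins, 25 had a lower mean log2 value in HET and 5 a higher one, with a median of -0.09 against -0.17 for all genes, and the list did not pass (camera adjusted p = 0.922). Under median-ratio scaling the list's median was 0.10, and the list passed downward in 1 of 24 alternatives, the one without a filter on low values (adjusted p = 0.0218, range 0.0218 to 0.998). Ranbp2, which encodes a component of the cytoplasmic filaments, held 18.9 ± 3.66 FPKM in FL and 13.8 ± 3.24 in HET. Ahctf1, needed for pore assembly, held 19.8 ± 4.78 and 14.1 ± 2.23, and the nuclear basket gene Tpr 54.2 ± 10.7 and 43.3 ± 5.19. None of these 3 passed, although Ahctf1 did without FL 5 (limma adjusted p = 0.0498), and Nup214 was the 1 member that passed when adjusted over the list alone. Import and export receptors and their regulators, 31 tested, had a median of -0.10 and did not pass (adjusted p = 0.922), except downward without a filter (0.0249, range 0.0249 to 0.998).

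Across the 13041 tested genes, no gene passed. The smallest limma adjusted p was 0.281. At an unadjusted p under 0.05 there were 1355 genes, 188 higher and 1167 lower in HET, where 652 are due by chance if genes are independent, and 19 of 100 splits of the 10 libraries into groups of 5, the real one included, gave as many. The groups did not overlap for 66 genes, 0.506% of those tested, where chance gives 0.794%. The median log2 fold change was -0.17, and median-ratio scaling moved it to 0.005, and the levels below are given without this scaling unless it is named. The count was 409 without FL 5, of which 30 were higher and 379 lower, and 1 each without HET 1, HET 2 or HET 5. Without FL 5 and HET 1 it was 5954, a setting chosen after the data were seen. The median of all genes was -0.231 without FL 5 and -0.325 without FL 5 and HET 1. Neither fit was run on scaled columns.

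Among the genes with the smallest p, the lower ones included Gspt1, a translation termination factor, which held 21.6 ± 8.78 FPKM in FL and 7.96 ± 1.05 in HET. Naf1, an assembly factor of box H/ACA ribonucleoproteins, held 3.95 ± 1.81 and 0.878 ± 0.384. The kinase gene Pim1 held 66.3 ± 23.8 and 30.3 ± 7.76, and Fxyd1 3.99 ± 1.49 and 1.11 ± 0.757. The higher ones included Ly6c2 at 439.8 ± 150.1 FPKM in FL and 798.5 ± 204.1 in HET, the immunoglobulin heavy chain gene Ighm at 1006 ± 424 and 11350 ± 12560, and the light chain segment Igkv1-88 at 5.44 ± 7.32 and 125.9 ± 129.4. Mmp9 held 0.474 ± 0.215 and 1.56 ± 0.479, Hist2h2ab 2.99 ± 1.11 and 7.72 ± 3.20, and Zakit 0.450 ± 0.542 and 1.86 ± 0.854. All of these had limma adjusted p = 0.472, and each lay on the same side of the FL median in all 5 HET libraries. Without FL 5, Gspt1, Naf1, Pim1 and Mmp9 passed, with limma adjusted p of 0.00564, 0.00564, 0.0279 and 0.0496.

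Ferroptosis genes gave no difference past the threshold in the full set of libraries. Gpx4, the peroxidase that reduces lipid hydroperoxides, held 628 ± 29.2 FPKM in FL and 633 ± 100.2 in HET (SD, n = 5). The ferritin genes Fth1 and Ftl1 held 2754 ± 235 and 5314 ± 568 FPKM in FL, and 2531 ± 513 and 4639 ± 536 in HET. The transferrin receptor gene Tfrc held 21.9 ± 4.81 and 25.2 ± 7.20, Acsl4, which loads polyunsaturated fatty acids into lipids, 8.68 ± 1.89 and 7.20 ± 2.76, and the ferritinophagy receptor gene Ncoa4 111.5 ± 9.46 and 123.8 ± 23.4. The heme oxygenase gene Hmox1 held 37.74 ± 12 and 21.43 ± 17.98 and Aifm2 4.02 ± 1.34 and 2.69 ± 0.760. The cystine transporter gene Slc7a11 held 0.656 ± 0.370 and 0.562 ± 0.438 and was below the filter. The limma adjusted p of the tested ones ran from 0.472 for Hmox1 and Aifm2 to 0.992 for Gpx4, and the fold changes of Gpx4, Fth1 and Ftl1 turned from below to above 0 under median-ratio scaling. With sample quality weights, which count FL 5 and HET 1 least and were chosen after the data were seen, Acsl4 (-0.546, limma adjusted p = 0.00350, range 0.00204 to 0.9998) and Aifm2 (-0.600, adjusted p = 0.00860, range 0.00828 to 0.9998) passed downward, as they did without FL 5 and HET 1. The other 6 tested genes of this group passed in neither setting. Of all 13041 tested genes, 6869 passed with the weights and 5954 without FL 5 and HET 1. Such calls are therefore not particular to ferroptosis genes.

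Of 23 ferroptosis suppressors 22 had a lower and 1 a higher fitted value in HET, and of 24 drivers 20 were lower and 4 higher, with medians of -0.21 and -0.23 and camera adjusted p of 0.396 and 0.505. Under median-ratio scaling these medians were -0.029 and -0.046, so little of them lay beyond the shift of all genes. Among suppressors the smallest p belonged to Txnrd1, thioredoxin reductase, at 41.5 ± 13.1 and 25.4 ± 6.11 FPKM, and Gclc, of glutathione synthesis, at 3.71 ± 0.370 and 2.78 ± 0.472. Among drivers they belonged to Bach1 at 3.88 ± 0.873 and 2.40 ± 1.11 and Slc38a1 at 64.0 ± 9.48 and 51.1 ± 10.04. Iron handling genes (28 tested, 23 lower, median -0.16, adjusted p = 0.727) included Pcbp2, an iron chaperone, at 112.3 ± 11.9 and 87.5 ± 20.1, and Slc25a28 at 2.93 ± 0.550 and 1.93 ± 0.511. NRF2 and antioxidant genes (29 tested, 25 lower, median -0.11, adjusted p = 0.922) included Prdx1, a peroxiredoxin, at 394 ± 63.9 and 292 ± 33.1. Without a filter on low values, 1 of 24 alternatives for each, all 4 lists passed downward: suppressors at an adjusted p of 0.00142 (range 0.00142 to 0.978), drivers at 0.00928 (to 0.978), iron handling at 0.0218 (to 0.998) and NRF2 genes at 0.0467 (to 0.978). No member of these 4 lists passed when adjusted over its list alone. Without FL 5, Txnrd1 and Prdx1 passed over all genes, with limma adjusted p of 0.0211 and 0.0350. With quality weights all 7 genes named in this paragraph did, the highest adjusted p being 0.0239 for Gclc. These 7 were picked by their small p, and 6869 of all 13041 tested genes passed with the weights.

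**Figure D2:**
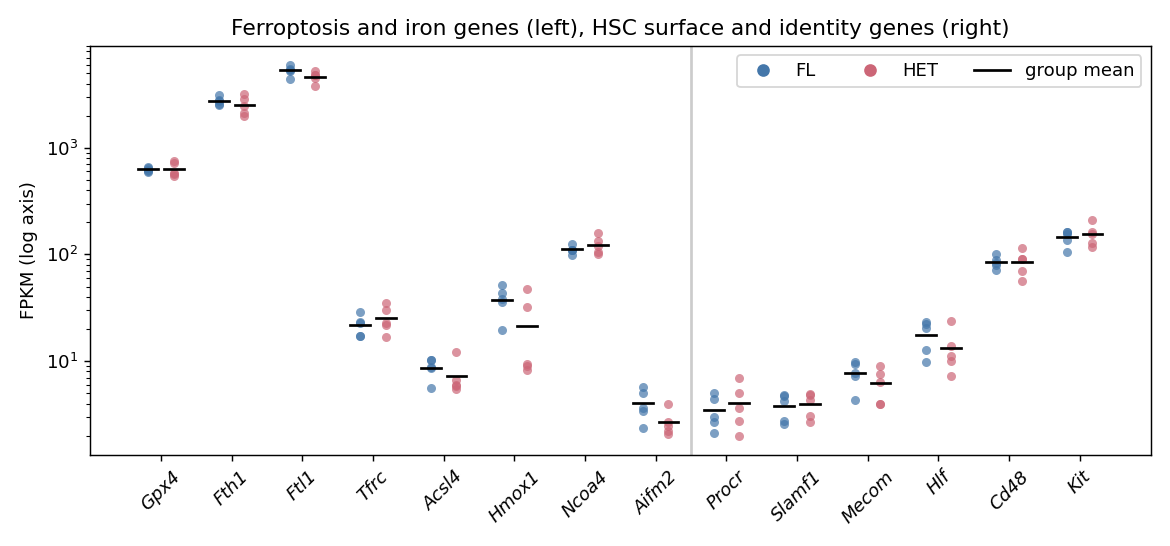
FPKM on a log axis of the fixed ferroptosis and iron genes and of the fixed HSC genes, with a point per library and a bar at the mean of each group of 5. Gpx4 means are 628 in FL and 633 in HET, and no gene shown passed the test.

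HSC genes were present in both groups. Procr held 3.45 ± 1.22 FPKM in FL and 4.06 ± 1.99 in HET, Slamf1, which encodes CD150, 3.81 ± 1.06 and 3.97 ± 1.02, Mecom 7.67 ± 2.16 and 6.19 ± 2.24, and Hlf 17.7 ± 5.97 and 13.3 ± 6.44. Kit held 144.9 ± 24.2 and 153.9 ± 35.8. Cd48, the transcript of the surface protein the sort selected against, held 85.1 ± 11.2 and 84.7 ± 22.6, and the granule genes Mpo and Elane, named after their values were seen, held 8250 ± 1147 and 3202 ± 921 in FL and 9573 ± 1937 and 3550 ± 1128 in HET. With these levels beside those of Slamf1 and Procr, whether the cells were the population in the labels is in doubt and was not tested. None of these 8 genes passed in the full set. Mecom and Hlf passed downward with quality weights and without FL 5 and HET 1, where 6869 and 5954 of all 13041 tested genes passed. Of 33 tested HSC identity genes 25 were lower and 8 higher (median -0.14, camera adjusted p = 0.922), with Prdm16 at 4.35 ± 1.14 and 2.49 ± 0.7099 and Cd34 at 327 ± 56.0 and 411 ± 58.7. Xist held 43.1 ± 8.97 and 42.9 ± 6.16, and the Y-linked genes Ddx3y and Eif2s3y were listed at 0 in all 10 libraries, while Uty held at most 0.28 FPKM and Kdm5d at most 0.08, both in HET 3.

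Neutrophil genes rose in HET relative to other genes. Of 18 tested members 17 were higher and 1 lower, with a median log2 fold change of 0.35, or 0.52 relative to all genes (camera adjusted p = 1.03e-15, and adjusted p = 0.0451 with an estimated correlation). The calprotectin genes S100a8 and S100a9 held 120.5 ± 37.6 and 31.3 ± 21.2 FPKM in FL and 313 ± 134.9 and 106.6 ± 49.2 in HET. Lcn2, a granule protein gene, held 6.65 ± 1.87 and 11.2 ± 2.99. S100a8, S100a9 and Mmp9 passed when adjusted over the list alone, each higher than the FL median in all 5 HET libraries, and no member passed over all genes in the full set. S100a9 passed over all genes without FL 5 (limma adjusted p = 0.0498). The call with an estimated correlation was lost under median-ratio scaling (adjusted p = 0.958, range 0.0145 to 0.958) and held in 5 of 23 alternatives. Non-robust shrinkage is among these 5, but it does not enter the list tests and only repeats the main result. Of 10 fits with 1 library left out it held in 2, those without HET 2 (0.0459) or HET 3 (0.0259), the highest p being 0.173 without HET 1.

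**Figure D3:**
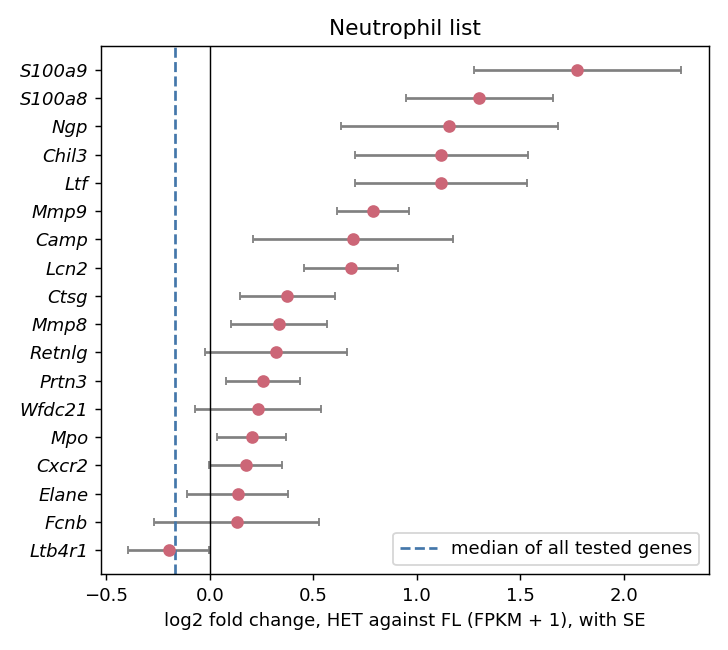
Log2 fold change of HET against FL, with its SE, for the 18 tested members of the neutrophil list, from 5 libraries per group, with a dashed line at the median of all tested genes. S100a9 is highest at 1.78 and Ltb4r1 is the member below 0.

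Ribosomal protein genes were higher in HET for 72 of 80 members (median 0.21, or 0.38 relative to all genes, camera adjusted p = 5.18e-22, but adjusted p = 0.978 with an estimated correlation). Rpl3 held 2135 ± 981 FPKM in FL and 3009 ± 757 in HET, Rpl4 3135 ± 932 and 4130 ± 871, Rpl6 1629 ± 577 and 2124 ± 511, and Rpl5, in the other direction, 1341 ± 385 and 779 ± 103. The median of the ribosomal protein genes turned to -0.039 with the ribosomal RNA level of each library as a covariate and to -0.096 with the first principal component. At the preset correlation the list's call was lost in 2 of 23 alternatives. These were the ribosomal RNA covariate (camera adjusted p = 0.356) and quantile normalization (median 0.077, adjusted p = 0.311). With the first principal component the list passed downward. Rpl5 passed over all genes without FL 5 (limma adjusted p = 0.00613). The list of ribosome biogenesis and MYC-related genes, called ribosome biogenesis below, includes box H/ACA and box C/D factors but also Myc, Mycn and Odc1. It had 29 of 33 members lower (median -0.16, camera adjusted p = 0.113). Dkc1, at 188.5 ± 28.5 and 130.2 ± 18.9, and Odc1, at 24.3 ± 6.84 and 14.3 ± 2.35, passed when adjusted over that list alone, and over all genes without FL 5 (limma adjusted p = 0.0325 and 0.0474). The list's median was 0.039 under median-ratio scaling. It passed downward without a filter (camera adjusted p = 2.05e-05, range 2.05e-05 to 0.998), and without HET 2 (camera adjusted p = 0.00412), HET 3 (0.0262) or HET 4 (0.0181).

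Markers of other blood cells gave 3 more calls at the preset correlation, and 1 came from metabolism. B cell markers had 7 of 11 members higher (median 0.08, camera adjusted p = 0.0123), with Igkc at 4664 ± 2826 FPKM in FL and 25320 ± 26640 in HET, and Ighm passed when adjusted over the list alone. HET 5 and HET 3 stood apart for both, at 68848 and 33060 FPKM for Igkc and 32051 and 14487 for Ighm, against at most 9860 and 4511 in the other HET libraries. T and NK cell markers had 8 of 13 higher (median 0.01, adjusted p = 0.00229), with Ncr1 at 0.972 ± 0.369 and 4.46 ± 3.31 and Klrb1c at 1.83 ± 0.430 and 4.08 ± 2.14. Genes of CD48-positive progenitors had 9 of 22 higher (median -0.05, adjusted p = 0.0386), a median below 0 in a list called upward relative to other genes, and Ighm and Ly6c2 passed over the list alone. Glycolysis genes had 13 of 24 higher (median 0.02, adjusted p = 0.00918), with Pgam1 at 341 ± 77.1 and 405 ± 53.1 and Ldhb at 49.5 ± 8.40 and 38.2 ± 12.3. With an estimated correlation the adjusted p was 0.961 for glycolysis and 0.978 for the other 3, so none of these 4 held. At the preset correlation, the B cell call was lost in 11 of 23 alternatives (highest adjusted p = 0.295), among them median-ratio scaling, no filter and the protein-coding subset, the progenitor call in 11 of 23 (0.676), the T and NK cell call in 5 of 22 (0.114), among them all 3 scalings, and the glycolysis call in 4 of 23 (0.640). The B cell losses included the fits without FL 1 (adjusted p = 0.0555) or HET 1 (0.0919), and the progenitor losses those without FL 2 (0.0569), FL 3 (0.211), HET 1 (0.297) or HET 2 (0.0520).

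Megakaryocyte markers were lower for 20 of 21 members (median -0.24, camera adjusted p = 0.166). Pf4, platelet factor, held 1757 ± 226 and 1110 ± 268 FPKM and Zfpm1, a partner of GATA factors, 5.75 ± 1.77 and 2.68 ± 0.757, and both passed when adjusted over the list alone. By mean log2 value, erythroid markers were lower for all 17 members (median -0.33, camera adjusted p = 0.640), although the mean FPKM of Car2 and Hbb-bs was higher in HET. Monocyte and macrophage markers were lower for 15 of 18 (median -0.36, camera adjusted p = 0.166), including Ms4a7 at 5.55 ± 2.12 and 2.37 ± 2.28. The member with the smallest p, Ly6c2, went the other way, at 439.8 ± 150.1 FPKM in FL and 798.5 ± 204.1 in HET. Under median-ratio scaling the medians were -0.057 for megakaryocyte, -0.124 for erythroid and -0.224 for monocyte markers. Without a filter all 3 lists passed downward, at adjusted p of 0.000605, 0.0218 and 0.00131, and over all alternatives the highest was 0.978 for each. Single left-out libraries brought these lists past the threshold: HET 5 for megakaryocyte (camera adjusted p = 0.00791), HET 2 (0.0121) or HET 4 (0.00137) for erythroid and FL 3 for monocyte markers (0.00497). Zfpm1 passed over all genes without FL 5 (limma adjusted p = 0.0180). Of the 40 lists, 6 passed at the preset correlation, all upward, 1 with an estimated correlation and 0 with fry, whose smallest adjusted p was 0.373 for a shared direction and 0.209 for either direction. The lists for mast cells and basophils, dendritic, endothelial and stromal cells, quiescence, S and G2/M phase, p53, interferon, NF-kB, immediate early, heat shock, unfolded protein, oxidative phosphorylation, mitochondrially encoded, hypoxia, cholesterol, fatty acid, heme, apoptosis, DNA repair, autophagy and Hox-related leukemia genes did not pass, with adjusted p from 0.0682 for heat shock to 0.922 for cholesterol synthesis.

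Libraries did not separate by genotype along the main axis of variation. The first principal component held 42.6% of the variance and the second 13.3%. FL 1 to 4 lay at -0.344, -0.365, -0.270 and -0.169 on the first and HET 1 at -0.400 beside them, while HET 2 to 5 lay at 0.309, 0.246, 0.355 and 0.352 and FL 5 at 0.287. By Spearman correlation across genes, the nearest library to FL 5 was HET 2 (0.963) and the nearest to HET 1 was FL 3 (0.961). The ribosomal RNA gene CT010467.1, named after its values were seen, held 15046, 14386, 27597, 24257 and 50918 FPKM in FL 1 to 5 and 30063, 32982, 59747, 39697 and 39024 in HET 1 to 5. Nup214 in FL 5 and HET 1, at 30.0 and 31.2 FPKM, lay between the values of FL 1 to 4 and those of HET 2 to 5.

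**Figure D4:**
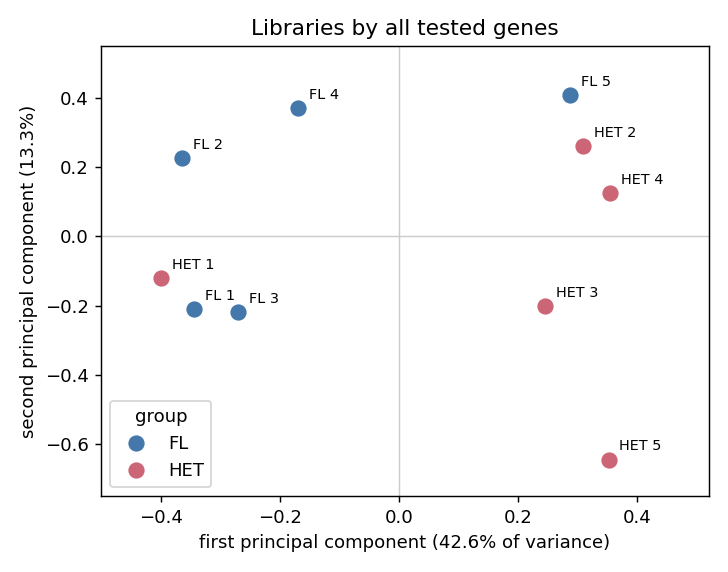
The 10 libraries on the first and second principal components of log2(FPKM + 1) over all tested genes, holding 42.6% and 13.3% of the variance, coloured by group. FL 5 lies at 0.287 among HET 2 to 5 and HET 1 at -0.400 beside FL 1 to 4.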

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

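The tests of exchanged labels, ribosomal RNA and depth below were chosen after the result was seen. In 8 of 114 groups of 5 libraries, 1 library lay far from the other 4, where chance gives about 5.7. The gap to the nearest library, as a share of the group's whole range on the log2 scale, exceeded 0.71 in each. HET 1 was highest among HET libraries for Acsl4 (0.757, at 12.1 FPKM), Ranbp2 (0.765, at 19.5 FPKM), Ldhb (0.731, at 59.7 FPKM) and Pcbp2 (0.810, at 122.9 FPKM), and lowest on the first principal component (0.856). FL 5 was lowest among FL libraries for Acsl4 (0.730, at 5.54 FPKM), Rpl5 (0.781, at 683 FPKM) and Txnrd1 (0.738, at 19.5 FPKM). All 8 gaps belonged to FL 5 or HET 1.

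FL 5 and HET 1 lay with the libraries of the other genotype. Depth is argued against: 1 fragment was worth 0.063 FPKM per kilobase in FL 5, within the 0.045 to 0.069 of FL 1 to 4, and 0.075 in HET 1, within the 0.045 to 0.11 of HET 2 to 5. Exchanged labels and the true labels cannot be told apart from Nup214, since FL 5 lay 2.56 SDs above the mean of HET 2 to 5 and HET 1 3.25 SDs below that of FL 1 to 4 on the log2 scale, outside both ranges but inside the 95% prediction intervals, which reached 42.0 FPKM upward and 29.6 FPKM downward. A difference in RNA or library quality stays open and is a candidate explanation: ribosomal RNA in FL 5 was 1.85 times the highest of FL 1 to 4, and in HET 1 it was 0.911 times the lowest of HET 2 to 5. By this measure FL 5, at 50918 FPKM, lay within HET 2 to 5 (32982 to 59747). HET 1, at 30063, lay above all of FL 1 to 4 (14386 to 27597), so ribosomal RNA does not place it with them. A difference between mice or in the sorted cells stays open too, as untested.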

How the results depend on the processing

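The scalings, quantile normalization, protein-coding subset, quality weights, covariates and the fit without both FL 5 and HET 1 were tests chosen after seeing the data. TMM, size factors and other count normalizations, the other count test and voom were not run because the values are FPKM. The number of genes past the threshold stayed at 0 with a pseudocount of 0.1, without a filter, with the stricter filter, with non-robust shrinkage, at an adjusted p under 0.1, with a fold-change minimum, in the protein-coding subset and with either covariate. It was 1 under median-ratio, upper-quartile and quantile scaling, 6869 with quality weights (635 higher, 6234 lower; weights 0.236 for FL 5 and 0.149 for HET 1), and 5954 (448 higher, 5506 lower) without FL 5 and HET 1, with 5812 genes shared by the last 2 settings. Removing those libraries leaves genotype and the first principal component aligned, so these counts do not separate the 2. The median of all genes was -0.319 with quality weights and -0.325 without FL 5 and HET 1. Neither fit was run on scaled columns, so how many of the lower calls lie beyond this shift of all genes is not known. With single libraries left out the count ran from 0 to 409, the highest without FL 5. It was 1 without HET 1, without HET 2 (Gm22107, a small nuclear RNA) and without HET 5 (Gm3788, a pseudogene); the last 2 were chosen after their values were seen. The cause was not tested.

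Nup214 ran from -1.02 with the first principal component to -2.003 without FL 5 and HET 1, where it passed (adjusted p = 0.000157), as it did with quality weights (-1.955, adjusted p = 0.000376), and from -1.84 to -1.42 with single libraries left out. Its adjusted p over all alternatives ran from 0.000157 to 0.9998. The replicate block gave 0 genes, 5 lists and a Nup214 fold change of -1.59 (limma adjusted p = 0.110). Its smallest adjusted p was 0.0971 against 0.281 without the block, and 2434 genes against 1355 had an unadjusted p under 0.05. The correlations of deviations between libraries of the same number were 0.214, -0.172, -0.158, 0.230 and 0.146. For numbers 1 and 4 the library of the same number had the highest correlation, and for the other numbers it did not. These values go both ways, so whether the numbers pair the libraries is not settled.

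The lists past the threshold numbered 1 with an estimated correlation, 25 without a filter, where low genes that hardly vary join the comparison and the 4 ferroptosis, iron and NRF2 lists are among those past it, 3 with quantile normalization and 10 with the first principal component, and ran from 5 to 11 with single libraries left out. Of 55 genes that the naming rule gave beside Nup214, 40 passed with quality weights and 39 without FL 5 and HET 1. In these settings 6869 and 5954 of all 13041 tested genes passed, and many of the 55 were named for a small p. The neutrophil list passed at the preset correlation under every alternative run.

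Among named genes that did not pass, the fold change changed sign in these settings: Gpx4, Fth1, Ftl1 and Cd48 under median-ratio scaling (0.198, 0.059, 0.003 and 0.158) and upper-quartile scaling (0.200, 0.061, 0.006 and 0.160), Cd48 under quantile normalization (0.090), Gpx4, Fth1, Procr, Slamf1 and Kit with quality weights (0.118, 0.003, -0.244, -0.208 and -0.135), Tfrc, Acsl4, Hlf, Cd48 and Xist with the ribosomal RNA covariate (-0.035, 0.018, 0.042, 0.036 and -0.078), Tfrc, Acsl4, Mecom, Hlf, Cd48, Xist, Rpl4 and Rpl6 with the first principal component (-0.016, 0.142, 0.107, 0.137, 0.158, -0.105, -0.003 and -0.045), and Gpx4, Procr, Slamf1 and Kit without FL 5 and HET 1 (0.042, -0.10, -0.120 and -0.151). With single libraries left out, Gpx4 ran from -0.071 to 0.049, Slamf1 from -0.049 to 0.149, Cd48 from -0.161 to 0.098, Kit from -0.042 to 0.165, Procr from -0.045 to 0.311 and Xist from -0.058 to 0.114.

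The direction of a list is relative to other genes, so its median can keep its sign when the direction turns. It turned for ribosomal proteins with the ribosomal RNA covariate (-0.039) and the first principal component (-0.096, adjusted p = 8.98e-08). It also turned, with neither value past the threshold, for iron handling and NRF2 genes under the stricter filter (-0.141 and -0.095) and for HSC identity without a filter (-0.141). Iron handling, NRF2, nucleoporin and HSC identity medians were 0.034, 0.041, 0.10 and 0.000 under median-ratio scaling, 0.037, 0.043, 0.102 and 0.003 under upper-quartile scaling (transport factors 0.093), -0.197, -0.178, -0.180 and -0.478 with quality weights (transport factors -0.134, erythroid -0.101, ribosome biogenesis -0.179), and -0.244, -0.223, -0.202 and -0.389 without FL 5 and HET 1 (transport factors -0.139, erythroid -0.300, ribosome biogenesis -0.228). Nucleoporins and HSC identity were at 0.059 and -0.035 under quantile normalization, and NRF2, nucleoporins and transport factors at -0.137, -0.112 and -0.122 in the protein-coding subset. With single libraries left out the medians ran from -0.177 to -0.074 for NRF2, -0.280 to -0.056 for HSC identity, -0.132 to -0.053 for transport factors, -0.147 to -0.051 for nucleoporins, -0.462 to -0.050 for erythroid and -0.206 to -0.10 for iron handling genes. Read totals were not used here, so how far depth limits low genes is not known, and the cause of these turns was not tested.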

Other observations

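The tests of B cell markers, of late against early neutrophil genes, of scaling and of the first principal component were chosen after the result was seen; so was the count of splits with at least 1 list at an estimated correlation. The other counts of splits and the test of plasma cell markers were fixed before they were run, that of the neutrophil list on a list picked after its p was seen. Transcripts on the marker lists of other blood cells were abundant in both groups, so the identity of the sorted population is in doubt and was not tested. The genes below were chosen after their values were seen. The primary granule gene Mpo held between 6828 and 11727 FPKM across the 10 libraries, and Pf4 group means were 1757 in FL and 1110 in HET. Immunoglobulin gene segments summed to 171771 of 1066190 FPKM in HET 5 and 81244 of 1038934 in HET 3, against 22594, 15490 and 22993 in HET 1, HET 2 and HET 4 and 4079 to 25046 in the FL libraries. Of 85 tested immunoglobulin C and V genes, 72 were higher in HET, 46 were highest in HET 5 and 10 in HET 3, 56 in both together, and 9 had an unadjusted p under 0.05.

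Other splits of the libraries bear on the counts. In 100 of the 126 splits of the 10 libraries into groups of 5, drawn with a fixed seed and the real one included, all 100 gave at least the 0 genes of the real split, as any split must, so that number tests nothing. The highest other split gave 3891, with FL 1, FL 2, FL 3, HET 1 and HET 3 on one side. That count of 3891 points to a structure of the libraries that the labels of genotype do not follow, and whether exchanged labels of FL 5 and HET 1 take part in it was not tested. The real split's 6 lists at the preset correlation were reached by 91 splits, the highest other giving 28, so chance is not excluded for that count. At least 1 list with an estimated correlation came from 3 splits, the highest other giving 1, and a p of the neutrophil list as small as 0.00113 came from 3, the smallest of the others being 0.000716. Both shares are under 0.05, but the neutrophil list was picked from 40 after its p was seen and its call held in 5 of 23 alternatives, so chance is left open for it.

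Of the 85 immunoglobulin genes, 46 were highest in HET 5 and 10 in HET 3. RNA of plasma cells is a candidate source. Of 20 detected plasma cell genes that are not immunoglobulin segments, 14 were highest in HET 3 or HET 5. Of these, 13 were highest in HET 5 and 1 in HET 3. Equal chances for all libraries would give 20% (exact one-sided binomial p = 1.85e-06, with genes that are not independent). The share of all tested genes highest in HET 3 or HET 5 was not computed, so that 20% is an assumed baseline. Jchain held 954.57 FPKM in HET 5, but 723.99 in FL 3, 359 in HET 1 and 199.69 in HET 3 and is also on the B cell list, while 14 of the 20 genes, all detected across the libraries, lay above every FL library in HET 5, 10 in HET 3, 7 in HET 1, 3 in HET 4 and 0 in HET 2. B cells cannot be told apart from no B cells by the same test, since 2 of 10 detected genes were highest there (exact binomial p = 0.624, upper limit 55.6%). Whether the lineage-negative gate of the labels removes both cell types was not tested, and a genotype difference stays open, as untested.

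The neutrophil list rose in HET relative to other genes. The first principal component and scaling are argued against as the whole cause of the raised median only. Relative to all genes it was 0.559 with that component as a covariate and 0.484 under quantile normalization, against 0.520 before (preset camera adjusted p = 0.000764 and 6.09e-05). The quartiles of members were 0.210 to 1.04 before, 0.157 to 0.908 with the covariate and 0.263 to 1.15 under quantile normalization. The estimated-correlation call ended in both (adjusted p = 0.851 and 0.904), where the list's estimated correlation was 0.167 and 0.211 against 0.140, so the call is not kept there. For that call the first principal component and scaling both stay open. RNA of mature neutrophils stays open and may contribute, although the gate in the labels excludes these cells. The list's 13 genes of late maturation had a median of 0.692, 12 of them above 0, against 0.202 for its 5 early granule genes. Both sets are members of the list whose rise is in question. The 12 genes above 0 therefore restate that rise and are no separate support. S100a8 held 313 ± 134.9 FPKM in HET. A genotype effect stays open, as untested.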
